A study of Papio anubis with 767 samples.

How the data were processed

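The series holds RNA sequencing of polyA-selected, stranded libraries from 64 tissues of the olive baboon (Papio anubis). By the labels, 12 males kept under 12 h of light and 12 h of dark and fed at set times were sampled every 2 h, 1 animal per time from ZT0 (lights on) to ZT22. Every tissue has 12 libraries except the iris, which has 11 (no ZT22), so 767 libraries were used. The animal of a given time is the same in all tissues by the labels, so time of day and animal are confounded throughout, and the 12 animals are the replicates of every rhythm test.

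The deposited table holds FPKM values made by the authors for 29202 rows with Ensembl identifiers, of which 20432 carry a gene symbol of their own and 8770 do not. The submitters' processing notes name STAR, featureCounts and DESeq2; their versions, their roles and the genome build are not given in the sources used here. Checked on the values, every entry of the 26546 rows above 0 was a whole number of reads, within 0.01 read, times a step for its gene and a step for its library, and the library steps equalled median-of-ratios factors to within 1e-09, so libraries were scaled by these factors and not by their total reads. Dividing by these steps gave back the reads assigned to genes: 32790 to 31.8 M per library, median 8.26 M, quartiles 6.15 M and 10.7 M. The median library had 44.2% of rows at 0. No columns were identical and none was left unmapped. For 8 columns the name carries the suffix approx, which neither the labels nor the table explains.

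Values were taken as log2(FPKM + 0.5). Within a tissue, genes with a mean of 1 FPKM or more were tested for a 24 h rhythm by fitting a cosine and a sine term, with the moderated F of limma 3.58.1 (variance trend on) in R 4.3.3, and Benjamini-Hochberg adjustment over the genes of that tissue at 0.05. The amplitude on the log2 scale, its standard error and the peak time follow from both coefficients, and fold is the fitted peak over the fitted trough. For the body-wide test each library was centred on its tissue's mean and the deviations were averaged per animal over the 63 tissues with 12 libraries, for genes that passed the filter in at least 0.5 of them. The same was done for 22 brain tissues and for 35 peripheral tissues; 7 eye and gland tissues belonged to neither class. The difference between brain and periphery was tested on the brain minus peripheral value of each animal, as labelled. Core clock calls in single tissues were adjusted over the list alone as well as over all genes of the tissue.

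A gene was called tissue-enriched when its mean over a tissue's libraries was at least 5 FPKM and 5 times that of the next tissue, with an adjusted p under 0.05 from limma paired by labelled animal. Gene lists were fixed before the data were examined, as were the tests, the tissue classes and the first set of other settings. For each list and place the mean z-score of the measured members was computed per animal, and its 24 h fit was tested against 1e+05 random orders of the animals (permutation test, 60 pairs of list and place, adjusted together). Marker lists of cell types, also fixed beforehand, gave the median marker level of each library. A library was taken to hold another tissue's markers when a foreign list had a median of at least 10 FPKM and 20 times the tissue's median, or to lack its own when that list fell below the tissue's median by the same factor. Content shared by most libraries of a tissue cannot be flagged in this way. Of the libraries labelled adrenal cortex only those of ZT8 and ZT10 were flagged. No omental fat library was left out for smooth muscle.

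Named genes follow a rule also fixed beforehand: every member of both clock lists; the 15 genes called body-wide with the smallest p, the 5 with the largest fold at a mean of 5 FPKM or more and the 10 called in the most tissues; the 8 with the smallest p for the brain-periphery difference; in 12 chosen tissues the 3 genes with the smallest p at a mean of 5 FPKM or more; in each tissue the 2 enriched genes with the largest ratio; and members of the fixed lists. Rows without a symbol were passed over, and some genes named by this rule are not reported here. Genes used only as examples of a library's content (ALB, SNAP25, GKN1 and PMCH in the lungs) were chosen after their values were seen.

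A shared library axis was the first principal component of the libraries' deviations from their tissue means (12023 genes, without both clock lists). The iris and the 14 libraries far from their tissue had no part in defining it but were given scores. To test which animal a library came from, the axis was removed and the library's pattern over 200 genes with the largest share of animal-to-animal variance, measured in at least 30 tissues and with a 24 h share of at most 0.5, was correlated with each animal's mean over the other tissues. It was run in 2 passes, the second without the libraries that mismatched in the first. The form of this comparison was settled while looking at its outcome: simpler forms run before it gave the same shifted tissues, iris and cornea, and differed for a few single libraries. Libraries were never moved to another time or tissue, only left out in added alternatives.

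This first set held pseudocounts of 0.1 and 1, no filter and a filter of 5 FPKM, median-of-ratios and quantile scaling within tissues, an F without moderation, a rank test over 12 phases against 1e+06 random orders, a linear trend over collection order for the class tests, wider tissue classes, and leaving out each animal. Added after seeing the data were the trend in the single-tissue tests, the axis as a covariate, and leaving out the 8 approx libraries, the 14 libraries far from their tissue (median absolute log2 distance above 1), the 92 libraries that matched another animal and the 75 libraries with markers of another tissue or without their own. Tissues left with fewer than 9 libraries dropped out of the last group of alternatives. As a test of chance, the 12 animals were put in 100 orders, the real one included, and for each gene the values of randomly chosen animals were exchanged between the top tissue and the next, 100 times with the real one included. Since both tissues were chosen from the real means, such an exchange lowers the count by construction.

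The tests were tried on simulated data, with noise drawn independently for each gene. The shared axis of the libraries was not simulated, so the false calls below do not measure error among genes that move together. With 200 genes given a rhythm, 56.7%, 85.1% and 98.5% were recovered body-wide at log2 amplitudes of 0.25, 0.5 and 1, with 7 false calls. In single tissues the power was low: in the liver 0%, 11.9% and 65.2% were recovered at amplitudes of 0.5, 1 and 2, and in the suprachiasmatic nuclei 8.96%, 52.2% and 95.5%. For the tissue comparison 196 of 200 genes at a 5-fold difference were recovered with 9 false calls, and 100 of 100 rhythmic lists with 0 false calls. The order of genes along chromosomes was taken from a RefSeq annotation of assembly Panubis1.0, in which 9543 of 10523 named genes were matched (90.7%). Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and the R package data.table (version 1.17.8).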

Results

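Gene expression was measured by RNA sequencing in 64 tissues of 12 male olive baboons, each animal sampled at 1 time of a 24 h day in steps of 2 h. The tissues were grouped as 22 brain regions, 35 peripheral organs and 7 eye or gland tissues, with 12 libraries each (11 for the iris). Depth, as reads assigned to genes, ran from 32790 reads in the amygdala library of ZT8 to 31.8 M, with a median of 8.26 M. A median of 12398 genes per tissue reached a mean of 1 FPKM, from 10860 to 14420. Each time rests on 1 animal, so a difference between times is also a difference between animals.

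The first comparison asked which genes mark each tissue. Tissues were paired by the labelled animal. As given below, all thyroid libraries, 6 iris libraries and the cornea libraries of ZT12 and ZT14 matched another animal. Pairs with these libraries are therefore not within 1 animal. In the thyroid, TG, the precursor of thyroid hormone, had a mean of 6249.7 FPKM, 868 times that of the next tissue (log2 difference 11.53 ± 0.47 SE, higher in 12 of 12 labelled pairs). Lung libraries held the surfactant proteins SFTPC at 9053 FPKM (11.47 ± 0.52) and SFTPB at 2313 FPKM. The cornea had the corneal keratin KRT12 at 17179 FPKM (13.69 ± 0.31, higher in all 11 labelled pairs with the iris), and the pancreas the digestive enzymes CELA1 at 128879 FPKM and CPA1 at 102428 FPKM. In the liver the apolipoprotein APOA2 reached 16345 FPKM, 2921 times the next tissue. In the retinal pigment epithelium the visual cycle genes LRAT and RGR had 284 and 471 FPKM. Among brain regions, the cerebellum was marked by GABRA6, a GABA receptor subunit of granule cells (151 FPKM, log2 difference 6.69 ± 0.33), the substantia nigra by the dopamine transporter SLC6A3 (192 FPKM), and the putamen by the phosphodiesterase PDE10A (109 FPKM) and the receptor GPR52 (35.9 FPKM). The pituitary was marked by prolactin (PRL, 11777 FPKM) and TSHB (2514 FPKM), the heart by MYL7 (2520.0 FPKM) and LRRC10 (27.5 FPKM), the bladder by the uroplakins UPK1A (597 FPKM) and UPK3A (527 FPKM), and the duodenum by the calcium-binding protein S100G (14709 FPKM) and the hormone GIP (351 FPKM). By this rule 1176 tissue-enriched genes were called with limma in 41 tissues, 910 of them with a symbol, and none in the other 23 tissues. Testicles had the most (232), followed by liver (180), skin (131), bone marrow (109) and pancreas (77). A low count need not be a trait of the tissue, since content shared between labels fails the rule. CYP17A1 had 6585 FPKM in adrenal medulla, which had 1 enriched gene, and 1847 FPKM in libraries labelled smooth muscle. Stomach fundus and adrenal cortex, whose libraries were often nearest to each other as given below, had 0 each. In testicles the spermatid markers were at 907 FPKM at ZT2 and 1300 FPKM at ZT14 against a tissue median of 4.72 FPKM. Means of such genes can therefore rest on few libraries. There were 6734 genes expressed in all tissues at 1 FPKM, of 20407; at 0.1 FPKM the count was 10996, at 5 FPKM 2760, and at 1 FPKM in every library 1644.

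The content of some tissues departed from their labels. Libraries labelled adrenal cortex had the steroid genes CYP17A1 at 0.11 to 0.92 FPKM in 11 libraries and 33.3 FPKM at ZT10, and STAR at a mean of 0.20 ± 0.23 FPKM (SD, n = 12), and the smooth muscle genes ACTG2 at 11305 ± 4416 FPKM and DES at 3388 ± 1509 FPKM. Libraries labelled adrenal medulla had CYP17A1 at 6585 ± 3399 FPKM and STAR at 1897 ± 1257 FPKM. By correlation over 10093 genes, 7 of the 12 libraries labelled adrenal cortex were nearest to the stomach fundus library labelled with the next time (r from 0.971 to 0.989) and 3 were nearest to the omental fat library of the same time. Gastrokine GKN1, a stomach gene, reached 134098 FPKM in the adrenal cortex library of ZT4 and 139767 FPKM in the stomach fundus library of ZT6. It was at 29830 FPKM (ZT10) and 34133 FPKM (ZT12) in these labels, and at 5620 FPKM (ZT14) and 6025 FPKM (ZT16). As given below, every stomach fundus library matched the animal of the preceding time, and no adrenal cortex library matched another animal. Such pairs therefore matched the same animal. Both labels count as separate tissues in the peripheral and body-wide means. In omental fat the median smooth muscle marker was 1139.8 FPKM, against 4.61 to 18.3 FPKM at ZT0 to ZT6. In 4 organs, 8 libraries (liver ZT0 and ZT6, ileum ZT0 and ZT4, lungs ZT0, and kidney medulla ZT0, ZT6 and ZT8) held neuron, astrocyte and oligodendrocyte markers together. The synaptic gene SNAP25 was at 233 FPKM in liver ZT0 and 491 FPKM in ileum ZT0, and liver albumin (ALB) was 31841.4 FPKM at ZT0 and 11930.6 FPKM at ZT6 against 329160 FPKM at ZT4. In all, 126 of the 767 libraries were nearest to a library of another tissue.

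The next question was which genes follow the time of day across the body. The core clock genes did, with their peaks spread over the day. ARNTL, the transcription factor that drives the loop, peaked at ZT13.5 with a 3.37-fold range (log2 amplitude 0.88 ± 0.04 SE, n = 12 animals, adjusted p = 1.2e-06). Its partner NPAS2 peaked at ZT14.6 with a 1.70-fold range. The repressors of the loop peaked near dawn and in the morning, PER3 at ZT0.6 (2.72-fold, 0.72 ± 0.05), PER2 at ZT3.0 (2.46-fold), PER1 at ZT3.1 (4.91-fold, 1.15 ± 0.09) and CRY2 at ZT3.6 (1.83-fold), while CRY1 came late at ZT11.7 (1.56-fold). The nuclear receptors that repress ARNTL peaked late at night, NR1D2 at ZT22.0 (2.73-fold) and NR1D1 at ZT22.8 (3.502-fold). Among the output factors DBP peaked at ZT1.6 (3.26-fold), TEF at ZT2.1 (3.03-fold) and HLF at ZT1.7 (1.69-fold), opposite to their antagonist NFIL3 at ZT12.0 (2.02-fold). Of 18 core clock genes tested body-wide 17 were called with limma, and 17 adjusted over the list alone. RORA missed the threshold (adjusted p = 0.15). With the axis score of the libraries as a covariate 13 were called, and 16 adjusted over the list alone; over all genes the calls of CLOCK (adjusted p = 0.534, range over alternatives 0.000416 to 0.534), HLF (0.101, 0.000307 to 0.101), BHLHE40 (0.358, 0.00313 to 0.358) and BHLHE41 (0.211, 0.000289 to 0.211) were lost.

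**Figure D1:**
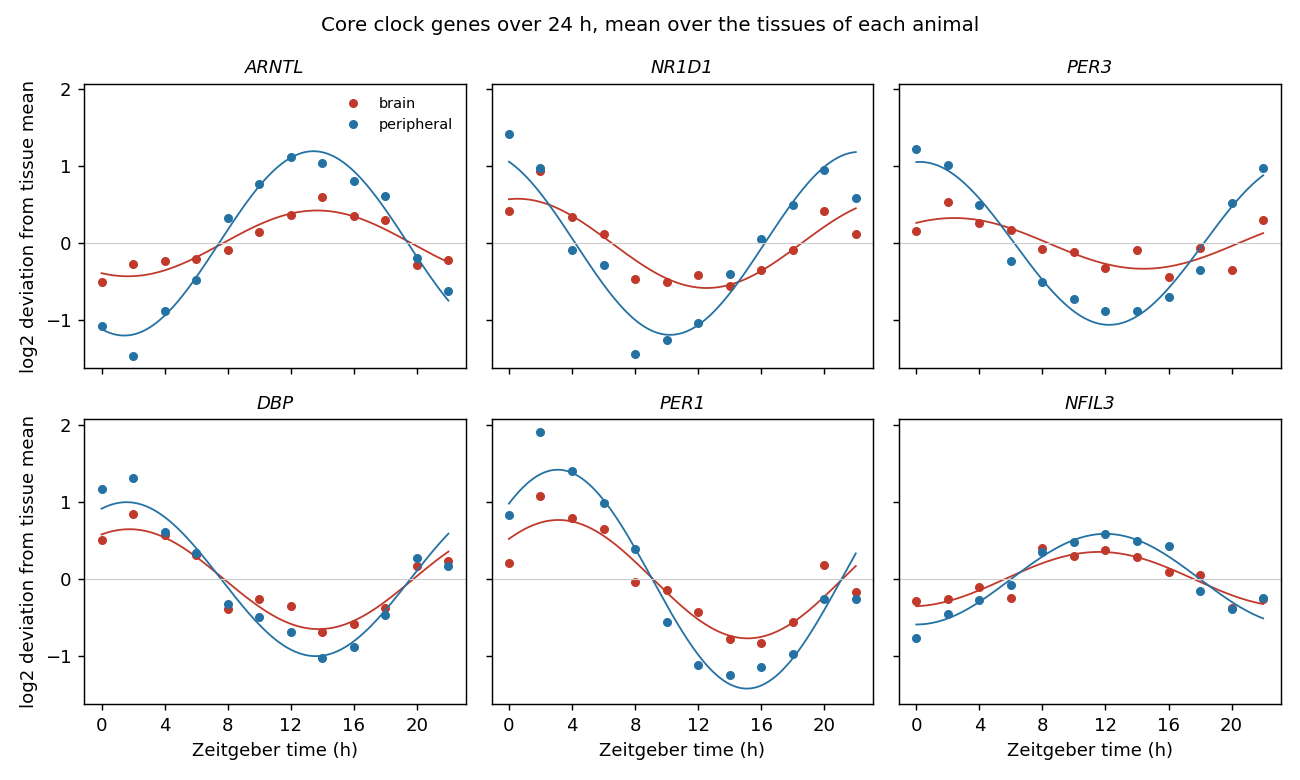
Log2 deviation from the tissue mean of 6 core clock genes against ZT (hours), 1 point per animal averaged over its brain or its peripheral tissues, with fitted 24 h curves. The ARNTL curve has an amplitude of 0.43 in brain and 1.20 in periphery.

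Within single tissues the same genes were followed 1 by 1. Adjusted over the list alone, ARNTL had a 24 h rhythm in 44 of 64 tissues, PER1 in 47, DBP in 43, NR1D2 in 40, PER3 and NR1D1 in 39, PER2 in 38 and TEF in 37, whereas CLOCK had 8 of 59. Adjusted over all genes of the tissue, ARNTL, PER1 and NR1D2 were each called in 23 tissues; with the axis as a covariate these were 13, 9 and 11, and 41, 44 and 38 adjusted over the list alone. Where called, ARNTL peaked at a circular mean of ZT13.6 (SD 1.34 h over tissues), and it was called in 30 of 35 peripheral and 10 of 22 brain tissues. In total 527 of 1106 clock gene and tissue pairs with a 24 h rhythm were counted adjusted over the list alone and 250 adjusted over all genes.

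**Figure D2:**
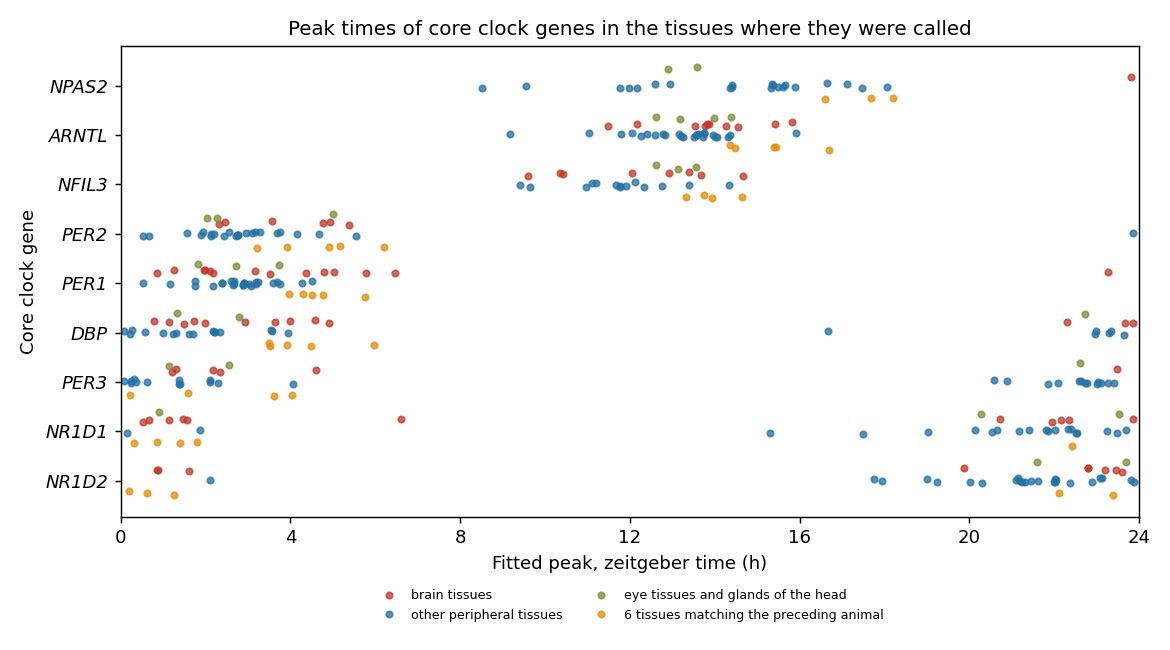
Fitted peak time (ZT, hours) of 9 core clock genes, 1 point for each tissue in which it was called after adjustment over the list alone. ARNTL clusters at a circular mean of ZT13.6 with an SD of 1.34 h.

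Genes of the clock-controlled list were also called rhythmic, but so were 62.2% of all genes tested body-wide. Of 14 measured members of the clock-controlled list 13 were called body-wide with limma (14 adjusted over the list alone), 8 peaking in the light phase and 5 in the dark phase. KLF15 (3.33-fold, ZT5.0) and KLF9 (2.64-fold, ZT4.4), transcription factors of metabolism that also answer to glucocorticoids, peaked in the light phase, as did TSPAN4 (3.20-fold, ZT5.4), CSNK1E, a kinase of the PER proteins (2.30-fold, ZT5.7), POR, the electron donor of cytochrome P450 enzymes (2.15-fold, ZT5.9), and PDK4, which limits glucose oxidation (2.90-fold, ZT7.1). COQ10B (1.48-fold) and NAMPT, an enzyme of NAD synthesis (1.30-fold), peaked at ZT18.3 and ZT18.7. None of these calls held over all genes with the library axis as a covariate (0 by limma, 4 adjusted over the list alone). The peaks named here lie in the same 2 spans, given below, as those of 92.5% of all genes called body-wide. Whether this list differs from genes at large was not tested.

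Many genes outside the clock lists had a body-wide rhythm. FCER1A, a chain of the IgE receptor of mast cells, peaked at ZT17.1 (2.06-fold, log2 amplitude 0.52 ± 0.04, adjusted p = 4.1e-05), and HNRNPDL, an RNA-binding protein, at ZT19.8 (1.61-fold, 0.34 ± 0.03). Around midday peaked the histone gene HIST1H2AC (3.06-fold, ZT6.9), the stress-responsive gene NDRG1 (2.46-fold, ZT7.1), the sulfur dioxygenase ETHE1 (1.96-fold, ZT5.4), ENHO, which encodes a secreted metabolic peptide (3.35-fold, ZT5.5), LCAT, which esterifies plasma cholesterol (2.72-fold, ZT6.2), and RBM14 (3.51-fold, ZT6.6). At night peaked BLOC1S6, a lysosome biogenesis gene (1.66-fold, ZT18.7), and the pyrophosphatase PPA2 (1.59-fold, ZT18.6). The largest folds were those of the metallothioneins MT2A (7.78-fold, ZT5.8) and MT1X (5.27-fold, ZT4.5), the ribosomal protein RPS28 (6.19-fold, ZT6.2) and the complex I subunits NDUFB7 (5.37-fold) and NDUFS7 (5.18-fold). SPSB3 was called in 22 tissues, and RPS28, the autophagy receptor SQSTM1, ABHD16A, TIMM17B and DPP7 in 21 each. In all, 7495 of 12055 genes (62.2%) were called, the body-wide rhythmic genes, and 92.5% of them peaked at ZT4 to 8 (4186 genes) or ZT16 to 20 (2748 genes).

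The size of this set depended on a shared axis among libraries. The axis, the first component of the libraries' deviations from their tissue means, held 28.7% of the variance. The iris, the libraries far from their tissue and the genes of both clock lists had no part in defining it. Its mean score per animal was -0.006 at ZT0 and 0.82 to 0.91 from ZT2 to ZT6. It then fell over 0.05 at ZT12 to -1.01 at ZT22, and the 24 h curve explained 84.0% of it. With the axis as a covariate 21 body-wide rhythmic genes were called, all of them among the 7495; with a linear trend over collection order the count was 1042 and with a filter of 5 FPKM 4794. The median log2 amplitude of the 7495 genes went from 0.26 ± 0.05 (median SE) to 0.08 ± 0.07 with the axis, so the fits lost both amplitude and precision. HNRNPDL (adjusted p = 0.00909 with the axis, range over alternatives 6.1e-05 to 0.00909) and FCER1A (0.0301, 1.6e-05 to 0.0301) were called in every alternative run, whereas RPS28 was at 0.431 (6.4e-05 to 0.431) and MT2A at 0.861 (8.3e-05 to 0.861) with the axis. MT1X was called in 13 of 26 alternatives. The share of light-half peaks among body-wide rhythmic genes was 59.0%, but 47.8% with median-of-ratios scaling within tissues and 43.1% with quantile scaling. Against the deposited scaling, the body-wide median gene moved by up to 0.08 (log2) with the former and 0.12 with the latter, both at ZT20.

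**Figure D3:**
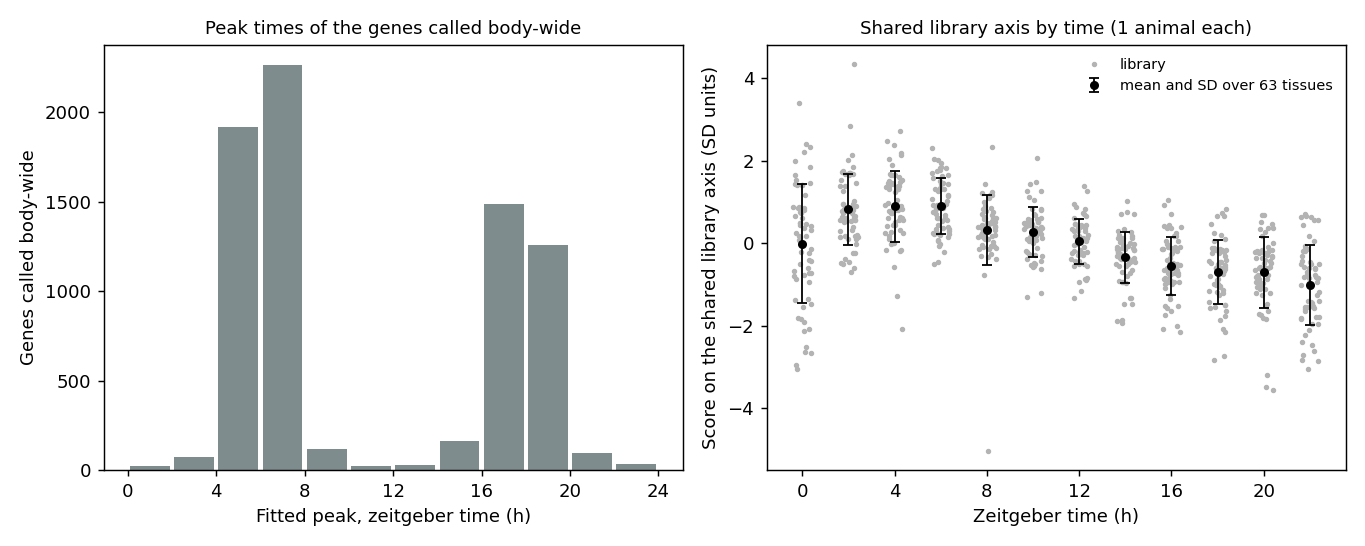
Left, number of body-wide rhythmic genes by fitted peak time in bins of 2 h; right, axis score of each library (SD units) against ZT, with the mean and SD over 63 tissues. The mean score is highest at ZT6 (0.91) and lowest at ZT22 (-1.01).

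Brain and periphery were then fitted apart. In brain tissues 10 of 17 core clock genes were called (11 adjusted over the list alone) and in peripheral tissues 17 of 18 (17), among them ARNTL in both. With the axis as a covariate 4 in brain and 13 in periphery were called (10 and 16 adjusted over the list alone), ARNTL in brain being at an adjusted p of 0.0972. Over all genes, 3743 of 12660 (29.6%) were brain rhythmic genes and 7184 of 11837 (60.7%) were peripheral rhythmic genes. With the axis as a covariate these counts were 6 and 30, with a linear trend 5 and 903, and with a filter of 5 FPKM 2314 and 4773. The brain count was 1761 by the rank test and 2318 without the animal of ZT6.

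Whether the rhythm differs between brain and periphery was tested within animals, as labelled. The peripheral class includes 6 tissues whose libraries all matched the animal of the preceding time, as given below. The peripheral value of a labelled animal thus mixes animals. The ARNTL amplitude was 0.43 in brain and 1.20 in periphery (log2; difference 0.77, adjusted p = 0.0047), that of NR1D2 0.33 and 1.03 (difference 0.70, adjusted p = 0.0041), that of PER3 0.33 and 1.06 and that of TEF 0.41 and 1.11. PER1 had 0.77 and 1.42, and DBP 0.65 and 1.00. Of 17 core clock genes tested 11 were called for the difference, and in all 11 the fitted amplitude was smaller in brain, at 0.20 to 0.65 of the peripheral one. With a linear trend 5 of the 11 were called, PER1 being at 0.357 and DBP at 0.335, and with the axis 7. Outside the clock, C19orf33 and the lectin FCN3 were called (difference amplitudes 1.27 and 0.77), as was PSMB8, a subunit of the immunoproteasome (0.49); C19orf33 and FCN3 were each called in 21 of 25 alternatives (with the axis 0.527, range 0.00233 to 0.527, and 0.533, range 0.00362 to 0.533) and PSMB8 in 24 of 26. The count of genes whose rhythm differs between brain and periphery, 612 of 10679, was not stable: it was 1 with an F without moderation, 6 with a linear trend, 9 with the axis, 242 without the approx libraries, 83 without those far from their tissue, 13 without those that matched another animal and 200 without those holding other markers. Leaving out the animal of ZT20 gave 18, of ZT8 31, of ZT4 33, of ZT16 211, of ZT22 312, of ZT12 366 and of ZT18 394. Among the named genes, NR1D2, ARNTL, NR1D1, PER3 and TEF lost the call only with the F without moderation (adjusted p from 0.066 to 0.0917).

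Single tissues differed in what they showed. In the liver the cholesterol synthesis genes HMGCS1 (60.9-fold, ZT16.1, adjusted p = 0.0148) and SQLE (24.8-fold, ZT16.1, adjusted p = 0.0271) peaked in the night, and UBE2QL1 at ZT3.7 (30.9-fold), between the liver libraries of ZT0 and ZT6 that held brain markers. In gastrocnemius muscle GATM, the first enzyme of creatine synthesis, peaked at ZT22.0 (4.79-fold, adjusted p = 0.0010) and SLC43A2, an amino acid transporter, at ZT10.3 (19.9-fold). In the heart HPF1, NLK and PKIA, a protein kinase A inhibitor, peaked at ZT16.5 to ZT17.6 (3.21-, 3.14- and 2.85-fold; adjusted p = 0.0176); the heart library of ZT4 held adipocyte markers (33.97 FPKM against a median of 1.36), and without that animal the heart had 3 calls instead of 4727. In kidney cortex SERF2, LCAT and the ion transporter SLC4A9 peaked at ZT4.4 to ZT5.5 (10.2-, 25.4- and 7.25-fold; adjusted p = 0.0468), and in subcutaneous fat the fibroblast marker THY1 at ZT5.1 (11.6-fold, adjusted p = 0.0462), beside skeletal muscle markers at 4670.3 FPKM at ZT4 against a median of 75.6. In libraries labelled adrenal cortex NUBP2 had a 14.2-fold range with its peak at ZT6.2 (adjusted p = 0.0122, range over alternatives 0.00761 to 1.00, called in 19 of 26), beside the smooth muscle content given above; without the animal of ZT6 these libraries had 2 calls instead of 2282. FAM127C in the suprachiasmatic nuclei, the seat of the central clock, had a 4.71-fold range (ZT3.8, adjusted p = 0.0173). In the retina the serotonin receptor HTR1F (4.88-fold, ZT19.8) had an adjusted p of 0.0650, and in prefrontal cortex RASD1 (9.50-fold, ZT8.8) one of 0.0788. The call of GATM was lost only with the axis (adjusted p = 0.0742, range over alternatives 0.000413 to 0.0742), whereas HMGCS1 was called in 16 of 25 alternatives, SQLE in 11 of 25, UBE2QL1 in 9 of 25, HPF1 and NLK in 22 of 26, PKIA in 21 of 26, SERF2 and LCAT in 9 of 26, THY1 in 11 of 26 and FAM127C in 16 of 26.

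Over all tissues, 52021 of 793508 gene-tissue pairs with a 24 h rhythm were called with limma, and 187614 (23.6%) passed an unadjusted p under 0.05. The most were in thyroid (5258), omental fat (4729), heart (4727), stomach fundus (4154) and ileum (3327), the thyroid holding skeletal muscle markers at ZT2 and ZT4 (22.4 and 164 FPKM against a median of 0.51), lymphocyte markers at ZT6 and pancreatic acinar markers at ZT18, and 11954 genes were called in at least 1 tissue. Smooth muscle markers in omental fat were at 4.61 to 18.3 FPKM at ZT0 to ZT6 against a median of 1139.8 FPKM. Without the libraries left out for markers omental fat had 2363 calls, heart 3, stomach fundus 4154 and ileum 3858. No omental fat library was left out for smooth muscle. Single animals decided many of these counts. Without the animal of ZT4 the heart had 3 calls, kidney cortex 0 instead of 1633 and omental fat 1113; without that of ZT18 the ileum had 0, without that of ZT0 visual cortex 0 instead of 2405. Leaving out 1 animal gave 7367 calls in the iris, where there were 0 (without ZT10). For 28 tissues limma called no gene, with 73 to 5908 genes at an unadjusted p under 0.05; in 3 of these the F without moderation made calls and in 1 the rank test. Among them were the pineal gland (314 genes before adjustment), pituitary (676), retina (1640) and prefrontal cortex (3564). The number of gene-tissue pairs with a 24 h rhythm was 29539 without a filter, 23723 without moderation, 12218 by the rank test, 23126 with a linear trend and 1905 with the axis. It was 21296 without the animal of ZT6, 22561 without ZT4, 23148 without ZT16, 27642 without ZT20 and 33301 without ZT12.

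Gene lists fixed beforehand gave coordinated profiles in few places. Glucocorticoid-responsive genes peaked together at ZT4.4 body-wide (permutation test, adjusted p = 0.0078), at ZT4.3 in periphery (0.0078) and at ZT4.4 in brain (0.0172). Of 12 measured members 10 were called body-wide, and 10 adjusted over the list alone, all in the light phase: FKBP5, a glucocorticoid receptor co-chaperone (2.55-fold, ZT3.8), TSC22D3 (2.68-fold, ZT4.8), ZBTB16 (3.96-fold, ZT4.5) and DDIT4 (2.16-fold, ZT3.0) among them, while DUSP1 and ERRFI1 missed the threshold. Heat shock chaperones peaked together at ZT9.6 in brain (adjusted p = 0.0078), where 8 of 14 members were called (9 adjusted over the list alone), with HSPB1 at 2.88-fold, BAG3 at 2.04-fold and FKBP4 at 1.71-fold. Cytosolic ribosomal proteins peaked at ZT8.0 in periphery (adjusted p = 0.0283), with 7 of the 7 measured members called there (7 adjusted over the list alone). The fixed list has 20 members, so most were not measured. Of all genes tested, 62.2% were called body-wide, 60.7% in periphery and 29.6% in brain. The permutation test asked whether a list mean follows a 24 h curve, and whether a list differs from genes at large was not tested. Body-wide RPS9 had a 3.80-fold range and RPL13 2.08-fold near ZT6.4, and RPL5 peaked at ZT17.4 (1.22-fold). Unfolded protein response genes peaked at ZT7.2 body-wide (adjusted p = 0.039), 7 of 10 members being called (7 adjusted over the list alone) against 62.2% of all genes, with CRELD2 (1.90-fold) and DDIT3 (1.71-fold) in the light phase and DNAJB9 (1.32-fold) at ZT18.9. These were 6 of 60 pairs of list and place; of 15 pairs of cell type marker list and class tested alike, 0 were called, 1 having an unadjusted p under 0.05. With the axis the glucocorticoid list was at 0.273 body-wide (range over alternatives 0.0033 to 0.273), 0.199 in periphery (0.0033 to 0.199) and 0.283 in brain (0.0036 to 0.283), and the heat shock list in brain at 0.0270 (range 0.0036 to 0.0386). With median-of-ratios scaling the ribosomal list (0.0551, range 0.00492 to 0.231) and the unfolded protein response list (0.176, range 0.00905 to 0.627) missed the threshold. The unfolded protein response list passed in 7 of 19 alternatives: it was at 0.0502 without the approx libraries and at 0.0550 to 0.116 without the animal of ZT0, ZT4, ZT6, ZT12, ZT14, ZT16, ZT18, ZT20 or ZT22. The ribosomal list passed in 11 of 19, being at 0.0729 without the libraries that matched another animal and at 0.0550 to 0.0699 without the animal of ZT4, ZT6, ZT12, ZT14 or ZT16. The glucocorticoid list in brain passed in 14 of 19, being at 0.0547 to 0.0612 without the animal of ZT12, ZT14, ZT16 or ZT18.

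Single members of the lists were also called within tissues, where no list passed as a mean profile. In the liver 11 of 20 cholesterol synthesis genes were called adjusted over the list alone and 4 adjusted over all genes, with fitted peaks from ZT15.6 to ZT18.2: MSMO1 (23.7-fold), IDI1 (17.9-fold) and CYP51A1 (14.02-fold) among them. The mean profile of this list had an adjusted p of 0.108, and the liver libraries of ZT0 and ZT6 held the brain markers given above. In kidney cortex the glucose production genes PCK1 (10.54-fold, ZT7.5), G6PC (4.86-fold, ZT8.4) and SLC2A2 (2.75-fold, ZT18.1) were called (mean profile 0.677). In the heart 8 of 11 oxidative phosphorylation genes were called adjusted over the list alone, NDUFV1 (9.85-fold) and CYC1 (8.88-fold) near ZT6 and NDUFS1 (1.59-fold) and ATP5C1 (1.67-fold) at ZT16.3 (mean profile 0.349), beside the adipocyte markers of the ZT4 library given above. In omental fat 9 of 10 adipocyte genes were called, both adjusted over the list alone and over all genes, CIDEA 59.4-fold and LIPE 47.6-fold, beside a smooth muscle marker level that was 4.61 to 18.3 FPKM at ZT0 to ZT6 against a median of 1139.8 (mean profile 0.0798). In the suprachiasmatic nuclei AVP, its main output peptide, peaked at ZT2.3 (28.5-fold), RGS16 at ZT2.6 (5.76-fold) and SIX6 at ZT6.9 (5.24-fold), each called adjusted over the list alone and none over all genes. By mean level AVP was highest in the supraoptic nucleus (16968 ± 40684 FPKM, SD). Next came the paraventricular nuclei (4221 FPKM) and the preoptic area (862 FPKM), so the suprachiasmatic mean was below each of these. Content from such neighbours in the suprachiasmatic libraries was not tested.

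Each library was also compared with the animals by genes that differ between animals and have at most 0.5 of that variance on a 24 h curve. In 6 tissues (ascending colon, descending colon, duodenum, stomach fundus, testicles and thyroid) all 72 libraries matched the animal labelled with the preceding time, with a median correlation of 0.85 (lowest 0.38) and a median of -0.07 with the labelled animal; all 72 did so too on genes with a 24 h share of at most 0.1. Of the other 695 libraries 675 (97.1%) matched their own animal (median r 0.84). The 20 others were 6 iris libraries, ZT10 to ZT20, that each matched the next animal, the cornea libraries of ZT12 and ZT14 that matched each other's animal, 7 of the 8 approx libraries, and 5 single libraries of amygdala, aorta, prefrontal cortex, prostate and pericardial fat. All peak times above use the labelled times.

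**Figure D4:**
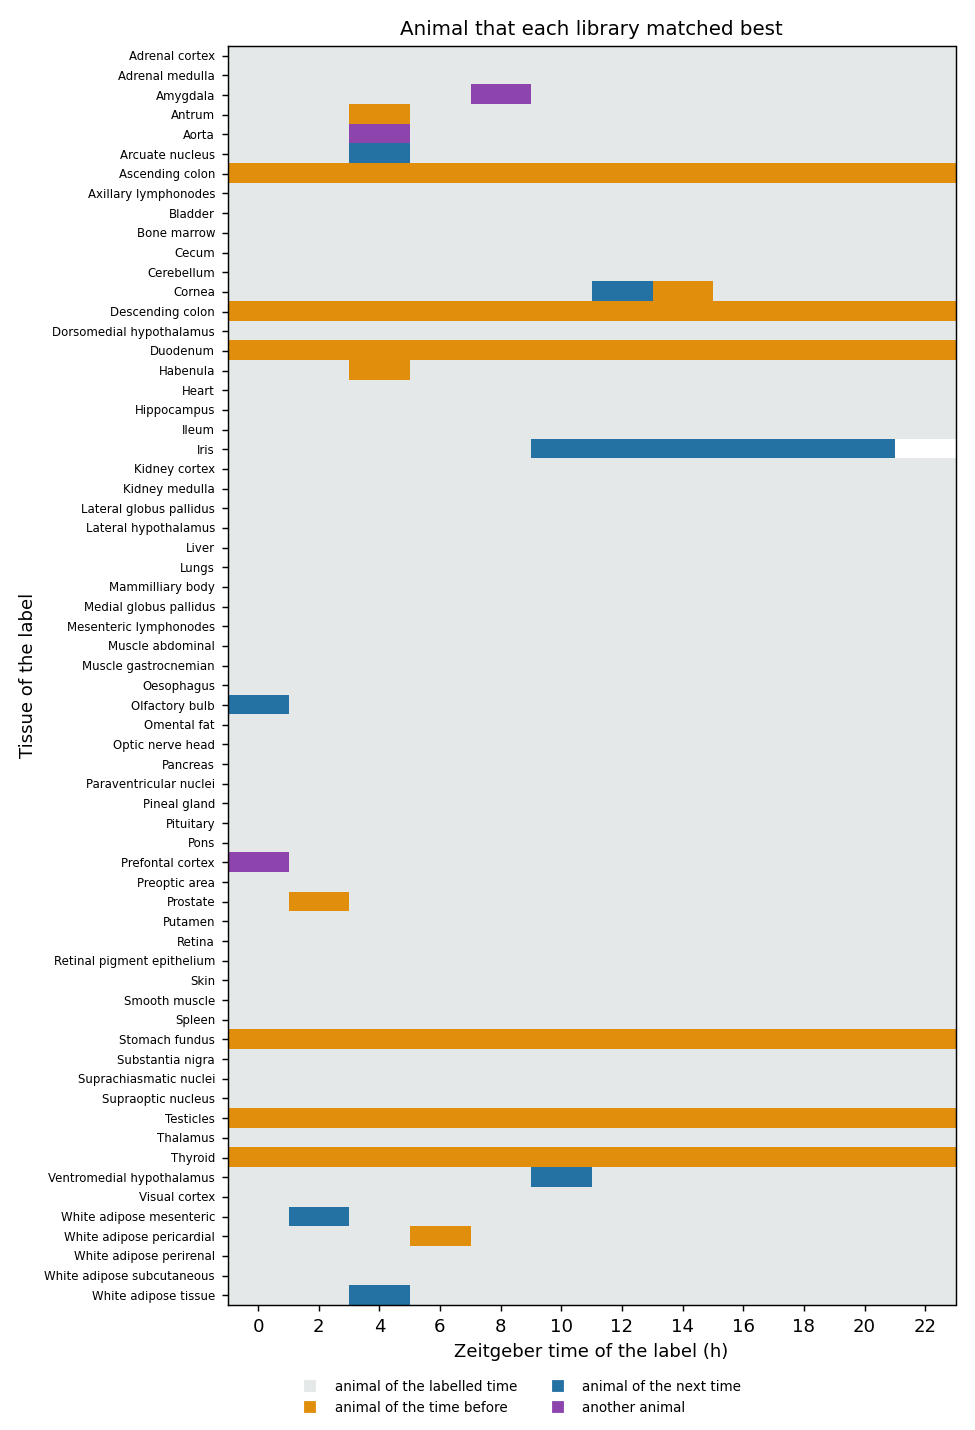
For each tissue (rows) and labelled ZT (columns), whether the library's animal-specific genes matched its own animal best or another. The 6 shifted tissues stand out as full rows, 72 of 72 libraries matching the preceding animal.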

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

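All tests of the explanations here were chosen after the result was seen, except the one on mislabelled samples for the midday and midnight peaks. The rhythm of 612 genes differed between brain and periphery. Among clock genes the difference had a log2 amplitude of 0.70 for NR1D2, 0.77 for ARNTL, 0.79 for NR1D1, 0.80 for PER3, 0.77 for TEF, 0.50 for PER2, 0.65 for PER1, 0.41 for CRY1, 0.48 for NPAS2, 0.40 for CRY2 and 0.35 for DBP. Outside the clock it was 1.27 for C19orf33, 0.77 for FCN3 and 0.49 for PSMB8.

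The smaller amplitude of core clock genes in brain could come from brain regions peaking at different hours, from lower levels near the floor, or from the shared library axis. Amplitudes fitted within each tissue do not depend on a common hour, and their median ratio of brain to periphery was still 0.42, so different hours can be excluded as the whole cause. Levels in brain had a median log2 ratio of 0.30 to those in periphery, and 6 of 11 genes were higher in brain; ARNTL, CRY1 and NPAS2 differed by -0.04 to -0.08 and PER3 by -0.34, which argues against lower levels for these 10, and NR1D2, at -1.15, leaves them open for itself. With the axis as a covariate 63.6% of these genes, 7 of 11, kept the call, which does not decide on the axis.

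In 6 tissues every library matched the animal of the preceding time, which could be a label carrying the next time, a later phase of the tissue, or a mixture of 2 animals. For 14 core clock genes peaks were compared in the 3 to 5 of these tissues where the gene was called. Testicles, with 0 such calls, had no part in this. The peaks were later by a median of 2.28 h than in other peripheral tissues, as a label shifted by 1 step of 2 h would give. A later phase was excluded, since 72 of 72 libraries matched the preceding animal on genes with a 24 h share of at most 0.1, which a phase does not move. A mixture was excluded for these libraries as a set by a median correlation of -0.074 with the labelled animal. The highest such correlation in a single library was 0.41, so a mixture in single libraries stays open.

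Most genes called body-wide peaked at ZT4 to 8 or ZT16 to 20, which could come from a composition bias of the libraries, from sequencing depth or from mislabelled samples. The axis loadings of chromosomal neighbours were correlated (rank correlation 0.53), as a composition bias that follows gene position would give. Without the libraries that matched another animal 6713 genes were called, 6585 of them also called with these libraries, and 92.4% peaked in the same spans, which excludes mislabelled samples as the whole cause. The rank correlation of axis score and reads had a median of -0.028 over tissues and was below 0 in 32 of the 64. This argues against depth acting in 1 direction over all tissues. The correlation ran from -0.71 to 0.66, so depth was not excluded for single tissues. A true effect of time of day stays open, since no time has a second animal, and GC content was not tested. A drift over collection order stays open too. The mean axis score was -0.006 at ZT0, 0.91 at ZT6, 0.05 at ZT12 and -1.01 at ZT22. A linear trend lowered the body-wide count, as given above, but it also takes part of a 24 h curve and cannot decide.

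Chance order of the animals was tested with 100 orders, the real one included. A value as large was seen once, in the real order alone, for gene-tissue pairs with a 24 h rhythm (52021, highest other 29762; before adjustment 187614, highest other 145882), body-wide rhythmic genes (7495, highest other 6211), brain rhythmic genes (3743, highest other 1793), peripheral rhythmic genes (7184, highest other 6400) and clock gene and tissue pairs with a 24 h rhythm (527, highest other 324), so 1 of 100 in each. For genes whose rhythm differs between brain and periphery it was 3 of 100 (612, highest other 973). There only 2 of the other orders called any gene, and each gave a count as large. This count therefore does not set the real order apart from them. Few other orders called any gene body-wide (2), in brain (2) or in periphery (3). For the results with 1 of 100, chance can be excluded for these orders at that share, and nothing more. For tissue-enriched genes 1 of 100 swaps, the real one, was as large (1176, highest other 753), but a swap lowers the count by construction, so this says nothing about chance. For light-half peaks among body-wide rhythmic genes 3 of 100 orders were as far from an even share (59.0%, highest other 64.3%), but only 2 of the other orders called any gene, so chance was not tested for the share.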

How the results depend on the processing

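The limits were 1 animal per time, no replicate of any time and a confounded shared axis. Reads per library went down to 32790 (amygdala, ZT8), and reads correlated with the axis score within tissues at -0.71 to 0.66, so depth may limit some of the calls in single tissues that the axis moved. All alternatives with the axis, or with approx, far, mismatched or marker-holding libraries left out, were added after the data were seen, as was the trend in single tissues.

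With the axis as a covariate, gene-tissue pairs with a 24 h rhythm numbered 1905 and gene-tissue pairs with a 24 h rhythm before adjustment 65312, body-wide rhythmic genes 21, brain rhythmic genes 6, peripheral rhythmic genes 30 and genes whose rhythm differs between brain and periphery 9; the light-half share of peaks was 57.1%, and gene list profiles numbered 1. The fitted peak of these named genes moved by more than 6 h with the axis and the call was lost: CSNK1D (adjusted p = 0.977, range 0.00116 to 0.977), NDUFB7 (0.682, 7.4e-05 to 0.682), NDUFS7 (0.475, 7.4e-05 to 0.475), TIMM17B (0.530, 7.4e-05 to 0.530), DPP7 (0.634, 8.0e-05 to 0.634) and FASTK (0.992, 7.4e-05 to 0.992). The cause was not tested.

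With a linear trend the gene-tissue pairs with a 24 h rhythm were 23126 and gene-tissue pairs with a 24 h rhythm before adjustment 110224, body-wide rhythmic genes 1042, brain rhythmic genes 5, peripheral rhythmic genes 903, genes whose rhythm differs between brain and periphery 6, and the light-half share 74.7%. A trend takes part of a 24 h curve sampled over 1 day.

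Without a filter there were 29539 gene-tissue pairs with a 24 h rhythm and a light-half share of 65.5%. At 5 FPKM fewer genes were tested, with 4794 body-wide rhythmic genes, 2314 brain rhythmic genes, 4773 peripheral rhythmic genes and a light-half share of 51.04%. The light-half share was 47.8% with median-of-ratios and 43.1% with quantile scaling. Without moderation there were 23723 gene-tissue pairs with a 24 h rhythm and 1 of the genes whose rhythm differs between brain and periphery; the rank test gave 12218 pairs and 1761 brain rhythmic genes. The median of z in place of the mean gave 11 gene list profiles. The count of genes expressed in all tissues was 10996 at 0.1 FPKM, 2760 at 5 FPKM and 1644 in every library. Without the block for the animal, tissue-enriched genes were 1210 against 1176.

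Genes whose rhythm differs between brain and periphery were 242 without the approx libraries, 83 without those far from their tissue, 13 without those matching another animal and 200 without those holding other markers. The light-half share was 61.4% without the far libraries and 63.7% without the mismatched ones.

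Leaving out 1 animal at a time gave 21296 to 64080 gene-tissue pairs with a 24 h rhythm, 160335 to 190046 gene-tissue pairs with a 24 h rhythm before adjustment, 6437 to 7485 body-wide rhythmic genes, 2318 to 4465 brain rhythmic genes, 6092 to 7095 peripheral rhythmic genes, 18 to 774 genes whose rhythm differs between brain and periphery, 470 to 530 clock gene and tissue pairs with a 24 h rhythm, a light-half share of 58.0% to 61.6% and 3 to 8 gene list profiles. Over all settings together, 181 counts stayed within 1.5 times or their interval, 43 fell below it, 2 rose above it and 13 shares moved; for named genes 2347 results kept their side of the threshold, 264 lost the call, 38 gained it and 6 had a moved peak.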

Other observations

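The tests of lists here were fixed beforehand, except those with the axis as a covariate, which were added after the data were seen. Neuropeptides of the hypothalamic and suprachiasmatic lists had their highest means in various places. Some leads were small, the second tissue having 3127 FPKM for OXT (paraventricular nuclei) and 121 FPKM for GHRH (arcuate nucleus). NMS was highest in the suprachiasmatic nuclei (44.8 ± 26.6 FPKM, SD, n = 12), the feeding peptides AGRP and NPY in the arcuate nucleus (497 ± 580 and 476 ± 472 FPKM), PMCH in the dorsomedial hypothalamus (7642 ± 6939 FPKM), HCRT in the lateral hypothalamus (435 ± 601 FPKM), CARTPT in the paraventricular nuclei (1037 ± 977 FPKM), OXT in the supraoptic nucleus (3295 ± 6753 FPKM) and GHRH in the mammillary bodies (135 ± 162 FPKM). Others were highest elsewhere, VIP in cecum (86.2 ± 52.1 FPKM), GRP in hippocampus (61.9 ± 19.997 FPKM), GAL in kidney medulla (293 ± 205 FPKM), NMU in oesophagus (61.0 ± 18.3 FPKM), CRH in thalamus (49.0 ± 29.1 FPKM), TAC3 in the medial globus pallidus (147 ± 136 FPKM) and POMC in the pituitary (1289 ± 1560 FPKM).

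The melatonin genes TPH1, AANAT and ASMT had means of 667 ± 345, 344.5 ± 171 and 2076 ± 1012 FPKM in the pineal gland, and limma called none rhythmic there (unadjusted p from 0.2204 to 0.342). The pineal library of ZT10 had ASMT at 1.91 FPKM and pinealocyte markers at 0.54 FPKM against a median of 561, those of ZT2 and ZT18 held choroid plexus markers (1261 and 508 FPKM against 11.5) and that of ZT6 anterior pituitary markers (753 FPKM against 0.41). In the retina the phototransduction genes GNGT1 (8922 ± 1684 FPKM) and SAG (2527 ± 950 FPKM) were highest, and RCVRN had 1097 FPKM there and 811 FPKM in the pineal gland. The calcium sensor GUCA1A was higher in the pineal gland (774 ± 509 FPKM) than in the retina (477 FPKM).

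Adrenal steroid genes were found in some libraries labelled smooth muscle. CYP17A1 was at 6468 FPKM at ZT2, 7399 FPKM at ZT10 and 7399.6 FPKM at ZT12, and from 0 to 334 FPKM in the others, and adrenocortical markers stood above the tissue median at ZT0, ZT2, ZT10 and ZT12. The smooth muscle gene ACTG2 ran only from 4.50 FPKM (ZT10) to 805 FPKM (ZT14) under this label. Gastric markers had a tissue median of 473 FPKM, and the stomach gene GKN1 ran from 15.3 FPKM (ZT12) to 98801 FPKM (ZT4). These libraries stayed in the peripheral class.

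Of 19 measured cholesterol synthesis genes 15 were called body-wide (16 adjusted over the list alone), 10 peaking in the dark phase and 5 in the light phase, where 62.2% of all genes were called; the mean profile of the list had an adjusted p of 0.451, and with the axis as a covariate 0 were called by limma, also 0 adjusted over the list alone. Of 11 immediate early genes 5 were called body-wide (4 adjusted over the list alone) and 0 of 11 in brain by limma.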
